A study of Homo sapiens with 28 samples.

How the data were processed

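Per the labels, nuclei were isolated from human brain tissue and libraries were made with 10x droplet 3' chemistry. Per the submitters' processing notes, reads were processed with Cell Ranger 7.0.0 on a GRCh38 reference, and Seurat 4.3.0 is named without a step. The deposited matrices hold raw UMI counts per gene and barcode from the authors, whole numbers without normalization. The notes do not state whether introns were counted or how barcodes were filtered. Read alignment and any correction for free RNA were not analysed here. The 28 libraries fall in 3 groups by their labels: N_SVZ (2), T_Mass (14) and T_SVZ (12). The labels give both tumor sites for 12 patients, and each library is 1 sample of 1 tissue, so that patients and not nuclei were the replicates.

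Feature lists differed: 24 libraries list 62696 genes and 4 libraries of 2 patients list 20030. The 20030 shared genes were used, and 20029 of them were matched to GENCODE v44. 45 genes of X inactivation or the Y chromosome were left out of all tests. Nuclei with at least 500 UMIs, at least 300 genes and at most 10% of UMIs from mitochondrially encoded genes were kept (116021 of 179980 barcodes). Doublet scores were computed per library with the Scrublet method in scanpy 1.11.5, and the highest share expected from loading was dropped (0.8% per 1000 nuclei, at most 10%). Counts were scaled to 10000 per nucleus and log transformed, and 2000 variable genes, 30 principal components, 15 neighbors and Leiden clustering at resolution 1 (leidenalg 0.10.2) gave 37 clusters, without batch integration. Clusters with a chromosome 7 minus chromosome 10 contrast of at least 0.5 log2 were named glioma-like, without a minimum marker score. Clusters at 0.2 or below were named after the class whose markers had the highest mean log2 fold over the summed profiles of reference classes, at least 1. Both also needed at least 3 markers of the class, each detected in 10% of nuclei, and no other class holding more of the 10 leading genes. These naming thresholds were set after the clusters were seen, and all other clusters stayed unnamed. The unnamed clusters enter the summed counts of all nuclei and the denominators of shares.

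Shares of nuclei in 8 classes were compared between T_SVZ and T_Mass with an exact sign-flip permutation test of the 12 paired differences (4096 sign patterns, smallest p 0.000488). T_SVZ and T_Mass were compared with N_SVZ by exact permutation of the libraries (91 and 120 groupings, smallest p 0.011 and 0.00833). All permutation tests were two-sided, and p was adjusted by Benjamini-Hochberg over the classes. On simulated shares, a shift of 10 points with an SD of 5 was called in 100% of 200 draws, and 10% of draws held a false call. The paired differences of glioma-like, oligodendrocyte-like, astrocyte-like, myeloid-like and neuron-like shares had SDs of 11.5 to 50.1 points, so this says nothing about the power in those classes.

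For genes, counts were summed per library and class, with at least 20 nuclei, and tested with edgeR 4.0.16 (filterByExpr, TMM, quasi-likelihood F test, package defaults, Benjamini-Hochberg at 0.05). Comparisons of T_SVZ with T_Mass had the patient as a block, a choice made from the series design before the data were examined. The pairing was checked once: the correlation of the 2 sites of a patient, after removing group means, was -0.0998 to 0.644 in glioma-like, -0.194 to 0.286 in myeloid-like and -0.134 to 0.238 in oligodendrocyte-like nuclei. The first fits used robust dispersions. After the calls of those fits and of limma-voom had been seen, the package defaults were kept, since the plan named no option, and the others became alternatives. Log2 fold changes are given with their SE from the fit, or as mean ± SD of log2 CPM (counts scaled to library size) with a prior count of 2.

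The genes named in the text follow a rule fixed at the same time: among genes past the threshold with an average log2 CPM of at least 4 and the sign of the fit in at least 75% of pairs or libraries, the 12 largest changes per direction, or, with fewer than 6 passing, the 6 with the smallest p, given as values and not as changes. Clone names, LINC, antisense and mitochondrially encoded genes were excluded there. Up to 4 members of each described list were added by smallest p, and 1 gene that this rule names is not reported here. Genes of at most 3 UMIs in both N_SVZ libraries are named without a fold change.

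The 25 gene lists and 11 marker sets were fixed in advance too and tested with camera of limma 3.58.1 (preset correlation between genes 0.01, lists of at least 3 tested genes, Benjamini-Hochberg over the lists of a comparison). Each was repeated with a correlation estimated from the residuals, and with fry. Lists are homeostatic microglia, monocyte-derived macrophage, lipid and SPP1 macrophage, antigen presentation by MHC class II, interferon response, inflammatory cytokines, complement and phagocytosis, hypoxia, glycolysis, mesenchymal-like, astrocyte-like, OPC-like and NPC-like states, cell cycle, neural stem and radial glia, extracellular matrix, angiogenesis, myelin, cholesterol synthesis, heat shock and unfolded protein, immediate early, synapse, iron and ferroptosis, mitochondrially encoded and ribosomal protein genes. Members were also adjusted over the list alone. The markers of the class under study were not tested within it, nor the glioma markers within glioma-like nuclei. B and plasma cell markers entered no comparison, since fewer than 3 were measured well enough.

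The libraries held a median of 20895880 UMIs, and the summed counts of a class rested on as few as 22 nuclei. The models were tested on simulated data with the same libraries: of genes given a log2 change of 1 and of 2, 0% and 1.03% were recovered in all nuclei, 1.01% and 57% in glioma-like, 28.7% and 95.5% in myeloid-like and 21.5% and 90.8% in oligodendrocyte-like nuclei against T_Mass, and 1.14% and 5.13% in myeloid-like and 4.17% and 33.7% in oligodendrocyte-like nuclei against N_SVZ. Each simulation gave 0 to 4 false calls. Counts were drawn independently for each gene at the trended dispersion. Against T_Mass, 3.05% to 4.01% of unchanged simulated genes had an unadjusted edgeR p below 0.05, but 0.478% to 1.81% of real genes. The simulations thus differ from the data, and their recovery may not hold there. Copies were looked for among 158 pairs of libraries within groups, and 0 were identical.

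Alternatives fixed in advance were DESeq2 size factors, no filter on low counts, DESeq2 1.42.0 in place of edgeR, at least 1000 UMIs per nucleus, doublets kept, at least 50 nuclei per library, Leiden resolution 2 (56 clusters), shares among nuclei that are not glioma-like, no patient block, an estimated correlation in camera, and each replicate left out. Alternatives chosen after seeing the data were edgeR with robust dispersions or bias-adjusted deviances, limma-voom, omission of 3 low-quality libraries or of the 4 libraries with the shorter feature list, omission of the 278 genes at 0 UMIs with the library of few genes, and the unnamed glial clusters counted as glioma-like. The analysis ran in R 4.3.3 and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.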

Results

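RNA of single nuclei was counted in 28 libraries from human brain tissue, with droplet 3' chemistry in which each captured RNA molecule carries a unique molecular identifier (UMI). The patients had glioblastoma, a malignant glial tumor of the brain. The subventricular zone lines the lateral ventricles and holds the neural stem cells of the adult brain. Tumor mass gave 14 libraries (T_Mass), the subventricular zone of patients with glioblastoma gave 12 (T_SVZ), and histologically normal subventricular zone gave 2 (N_SVZ). The T_SVZ and T_Mass libraries of 12 patients form pairs. The series was designed to set T_SVZ against T_Mass of the same patients, with N_SVZ as normal tissue.

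The deposited matrices held 179980 barcodes and 536408833 UMIs, with 287246 to 32498602 UMIs per library and a median of 20895880. UMI totals were 26451651 and 30082493 in the N_SVZ libraries, 1413888 to 32498602 in T_Mass and 287246 to 28738562 in T_SVZ. After filtering and removal of 5531 doublets, 110490 nuclei were kept, 87 to 11712 per library. The median number of UMIs per kept nucleus was 2864 and 4430.5 in the N_SVZ libraries, 665.5 to 4548.5 in T_Mass and 637 to 5082 in T_SVZ. Some genes were missing from the counts of some libraries. In 18 of the 28 libraries, at least 1 of 278 genes had 0 UMIs although 50 or more were expected. Of the 41 genes of the ribosomal protein list, 40 were among these 278. Ribosomal protein genes outside the list, such as RPS16 and RPSA, were among them too. In 6 libraries, 3 T_SVZ and 3 T_Mass, 50% or more of the 41 listed genes were at 0 UMIs. Whether genes were removed before deposit or counted in another way was not tested. In 1 T_Mass library only 1992 of the shared genes were detected, against 11743 or more in each of the others.

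The nuclei formed 37 clusters. Oligodendrocytes make myelin in the brain, and 5 oligodendrocyte-like clusters (19991 nuclei) were led by genes such as MOBP, TF and MOG. Myeloid-like nuclei (11029, in 5 clusters) were led by SLC11A1, TLR2, MSR1 and, in some clusters, by SPP1, by HK2, or by the immune and early response genes CCL3 and EGR3. Smaller classes were neuron-like (3229 nuclei; RALYL, CNTN5), astrocyte-like (2476; AQP4, GFAP, with HBB also leading 1 cluster), endothelial-like (1555; VWF, MECOM), T and NK lymphocyte-like (1064; CD2, CD96) and oligodendrocyte precursor-like (OPC-like, 714; TNR, PCDH15). Glioma-like nuclei (41997, in 10 clusters) were named by a contrast of chromosome 7 with chromosome 10 genes. It is the median log2 difference of chromosome 7 genes from the oligodendrocyte-like and myeloid-like clusters, minus that of chromosome 10 genes. The contrast was 0.74 to 1.51 in these clusters, against -0.07 to 0.14 in the other named clusters. Of the 32 glioma markers, 17 to 26 were detected per glioma-like cluster. Cluster 34 had 0 of them among its 10 leading genes. A further 6 clusters of glial nuclei (24622 nuclei) lay at 0.07 to 0.54 and stayed unnamed. Their mean share was 21.7% of nuclei in N_SVZ, 13.4% in T_Mass and 14.4% in T_SVZ. All unnamed clusters together held 30.3%, 24.2% and 25.2%. In single libraries they reached 97.7% of nuclei in T_SVZ and 100% in T_Mass. A low share of a named class in such a library can stem from unnamed nuclei.

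The first question was whether the subventricular zone of the patients held another mixture of cells than their tumor mass. Glioma-like nuclei made up 41.1% ± 42 of nuclei in T_SVZ and 42.9% ± 38.2 in T_Mass (mean ± SD, n = 12 pairs), and their share was lower in T_SVZ in 8 of 12 pairs. The unnamed glial clusters, not counted here, held up to 89.05% of nuclei in a T_SVZ library and 92.72% in 1 of the 14 T_Mass libraries. Myeloid-like nuclei, the microglia and macrophages, made up 12.5% ± 15.1 and 10.9% ± 8.44. Oligodendrocyte-like nuclei made up 10.1% ± 15.7 of T_SVZ and 11% ± 17.6 of T_Mass. Endothelial-like nuclei made up 2.06% ± 3.25 and 1.57% ± 2.37, with the higher share in T_SVZ in 9 of 12 pairs. T and NK lymphocyte-like nuclei made up 1.72% ± 2.88 and 1.1% ± 1.54, and OPC-like nuclei 0.385% ± 0.8 and 0.594% ± 1.18. Neuron-like nuclei made up 0.476% ± 1.07 of T_SVZ and 4.08% ± 11.3 of T_Mass, where 1 library reached 39.6% and the median was 0.114%. Astrocyte-like nuclei made up 6.54% ± 20.2 of T_SVZ and 1.43% ± 2.44 of T_Mass, and 1 T_SVZ library reached 70.5%. In exact sign-flip permutation tests of the mean paired difference, none of the 8 classes passed. The adjusted p was 0.933 for every class, and the lowest unadjusted p, 0.318, was that of neuron-like nuclei. The direction of the glioma-like, myeloid-like and lymphocyte-like differences turned without the libraries of the shorter feature list, to 12 points, -1.47 points and -0.0855 points. The astrocyte-like difference turned to -0.188 points without the low-quality libraries. At 1000 UMIs the oligodendrocyte-like difference turned to 0.02235 points, and among nuclei that are not glioma-like the OPC-like difference turned to 0.04171. With each pair left out, the neuron-like difference ran from -4.25 to -0.342 points and the astrocyte-like difference from -0.1492 to 5.999.

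**Figure D1:**
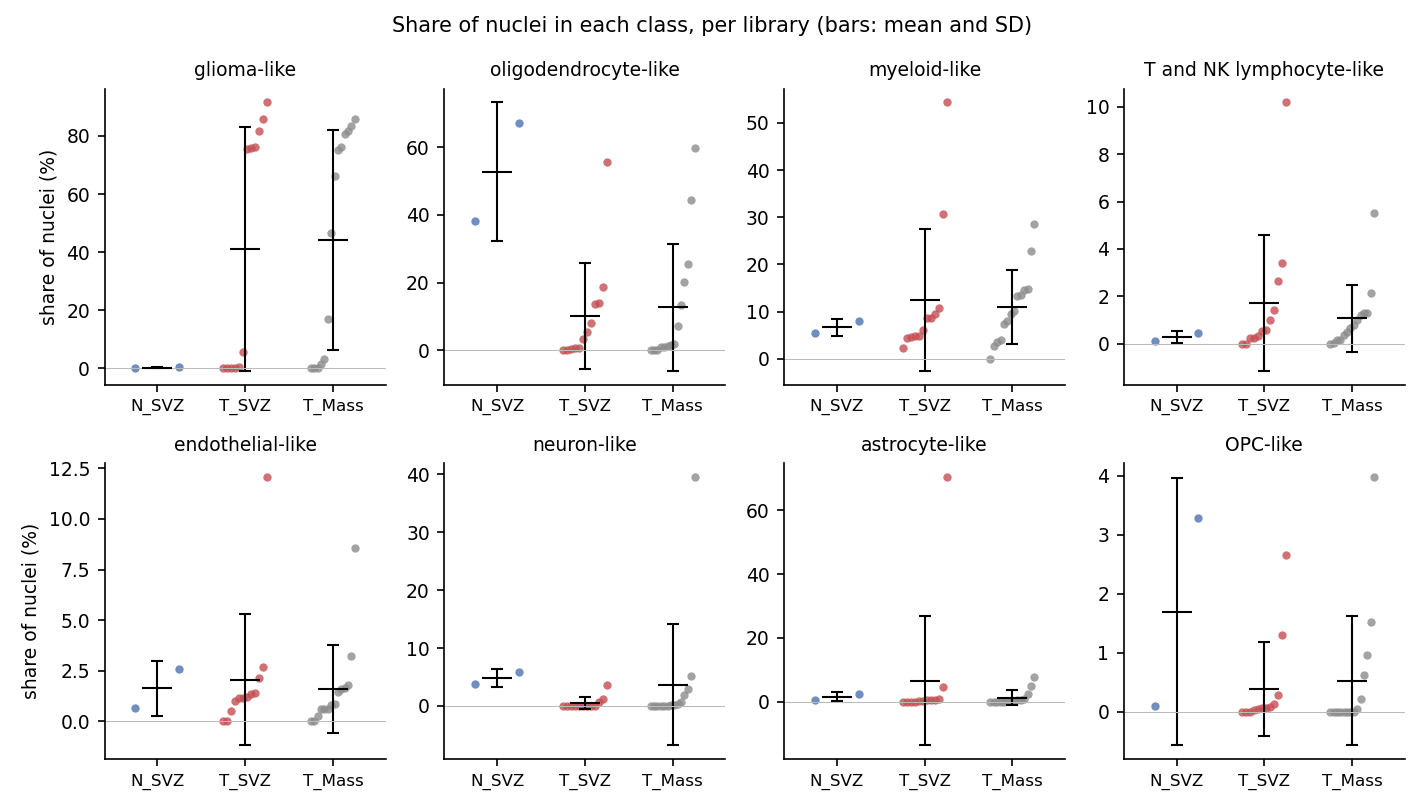
Share of kept nuclei (percent, vertical axis) in each named class, with 1 point per library for N_SVZ (2), T_SVZ (12) and T_Mass (14), and bars for the mean and SD. Oligodendrocyte-like nuclei made up 38.3% and 67.3% of the N_SVZ libraries, and T_SVZ and T_Mass libraries overlapped in every class.

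Against normal subventricular zone, the tumor libraries held smaller shares of oligodendrocyte-like and neuron-like nuclei, without passing the threshold after adjustment. Oligodendrocyte-like nuclei made up 52.8% ± 20.5 of N_SVZ (SD, n = 2) and 10.1% ± 15.7 of T_SVZ, and 11 of 12 T_SVZ libraries lay below both N_SVZ libraries (exact permutation test, p = 0.022, adjusted p = 0.0879). Neuron-like nuclei made up 4.81% ± 1.56 of N_SVZ and 0.476% ± 1.07 of T_SVZ, with 12 of 12 T_SVZ libraries below both (exact p = 0.011, the smallest this design can give, adjusted p = 0.0879). Glioma-like clusters held 0.264% ± 0.154 of N_SVZ nuclei, the background of this class in normal tissue, against 41.1% in T_SVZ (exact p = 0.308) and 44.1% ± 37.8 in 14 T_Mass libraries (exact p = 0.183). Myeloid-like nuclei made up 6.69% ± 1.83 of N_SVZ, 12.5% of T_SVZ (exact p = 0.648) and 10.9% ± 7.9 of T_Mass (exact p = 0.467). In T_Mass, oligodendrocyte-like nuclei made up 12.7% ± 18.8, and 12 of 14 libraries lay below both N_SVZ libraries (exact p = 0.025, adjusted p = 0.2, smallest possible p 0.00833). Neuron-like nuclei made up 3.65% ± 10.5 of T_Mass (exact p = 0.85). That difference ran from -2.261 to -0.05857 points with each N_SVZ library left out, and was 1.893 among nuclei that are not glioma-like. With each N_SVZ library left out, the oligodendrocyte-like difference ran from -57.19 to -28.18 points in T_SVZ and from -54.61 to -25.6 in T_Mass. Of the 8 classes, 0 passed an adjusted p of 0.05 in either comparison, and a single class could not pass even at the smallest possible p. Astrocyte-like, endothelial-like, lymphocyte-like and OPC-like shares had exact p of 0.0659 or more against T_SVZ and 0.167 or more against T_Mass. Unnamed clusters 13 (517 nuclei, all of N_SVZ) and 0 (67 of 68 of N_SVZ) scored highest for astrocyte markers. Among unnamed clusters, cluster 11 had the highest OPC marker score, with 1547 N_SVZ, 2154 T_Mass and 2353 T_SVZ nuclei. The astrocyte-like and OPC-like shares leave these nuclei out and so depend on the naming rule. A T_SVZ library with 97.7% unnamed nuclei and a T_Mass library with 100% count among those below N_SVZ.

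Counts of all kept nuclei were summed per library to show the tissue as a whole, cell mixture included, in 12 pairs. Vessel, microglial and myelin genes had positive medians in T_SVZ, and ribosomal protein and glioma marker genes negative ones. All 14 tested endothelial markers had positive log2 fold changes (median 0.86), among them EMCN (1.35 ± 0.69, SE), the transcription factor gene ERG (1.07 ± 0.63) and VWF (1.21 ± 0.72), an adhesion protein of blood vessels. All 12 genes of MHC class II antigen presentation were positive (median 0.73), with CIITA, the regulator of these genes, at 1.05 ± 0.72 and HLA-DPB1 at 1.06 ± 0.81. All 18 homeostatic microglia genes were positive (median 0.61), with OLFML3 at 1.31 ± 0.70 and the chemokine receptor CX3CR1 at 1.15 ± 0.80, as were all 25 myeloid markers (0.56) and all 17 oligodendrocyte markers (0.66), and 17 of 18 myelin genes (0.68), with MOBP at 1.55 ± 1.03. Of 41 ribosomal protein genes 40 were negative (median -1.25), and of 32 glioma markers 28 (median -0.32), with PTPRZ1 at -0.72 ± 0.88 and HILPDA at -0.76 ± 0.92.

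The median of all 15675 tested genes was 0.20 with TMM scaling and 0.28 with DESeq2 size factors. Without the genes at 0 UMIs and the library of few genes it was -0.0291. In that setting 7 of the 20 list calls given below ended, and the ribosomal list could not be tested. Relative to 0.20, the medians were 0.66 for endothelial markers, 0.53 for MHC class II, 0.40 for homeostatic microglia, 0.48 for myelin and -1.45 for ribosomal proteins. With limma's camera at a preset correlation of 0.01, 20 of 35 lists passed, 8 upward and 12 downward, and 0 of the 20 passed with an estimated correlation (adjusted p = 0.342 to 0.876; 0.794 for endothelial markers, 0.342 for ribosomal proteins, 0.873 for microglia, MHC class II and hypoxia). The other lists called upward were angiogenesis (median 0.50) and cell cycle (0.42). Hypoxia (21 of 29 negative, median -0.18; LDHA at -0.81 ± 0.78), glycolysis (12 of 16 negative, -0.17; GAPDH at -1.14 ± 1.37) and synapse (-0.05, positive with DESeq2 size factors) were called downward. GAPDH was among the genes at 0 UMIs, in 1 T_SVZ and 4 T_Mass libraries. Another 7 lists were called downward with a median above 0, so that median and test differed in sign: lipid and SPP1 macrophage (0.03), mesenchymal-like (0.05), neural stem and radial glia (0.07), mitochondrially encoded (0.09), NPC-like, for neural precursors (0.10), astrocyte-like (0.11), and heat shock and unfolded protein genes (0.12). The lists that did not pass were OPC-like (0.16), interferon response (0.36), complement and phagocytosis (0.41), monocyte-derived macrophage (0.18), inflammatory cytokines (0.03), extracellular matrix (0.21), cholesterol synthesis (0.21), immediate early (0.17), iron and ferroptosis (0.16), and the markers of OPC (0.57), ependymal cells (0.48), T and NK lymphocytes (0.46), mural cells and fibroblasts (0.26), astrocytes (0.16) and neurons (0.15). Adjusted over the list alone, 0 members of any list passed, as over all genes.

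For single genes, edgeR's quasi-likelihood test found 0 of 15675 changed, with 75 at an unadjusted p below 0.05 (0.478%, where chance gives 5%). DESeq2 found 0, with 608 unadjusted. The genes named by rule with positive values were SLC14A1 (1.73 ± 0.76), a urea transporter of astrocytes, NAA11 (1.68 ± 0.77), TTC6 (1.51 ± 0.76), CPVL (1.49 ± 0.78), ENPP6 (1.39 ± 0.76) and CYYR1 (1.22 ± 0.66), each in 9 or 10 of 12 pairs with adjusted p = 1. Those with negative values were RPS16 (-2.92 ± 1.38), RPSA (-2.72 ± 1.30), RPL7 (-2.67 ± 1.34), RPL13 (-2.55 ± 1.29), EEF1B2 (-2.34 ± 1.13) and RPL10A (-2.20 ± 1.15), parts of the translation machinery that have many pseudogene copies, and each was among the genes at 0 UMIs in some libraries. The self-test of this comparison recovered 1.03% of genes simulated at a log2 change of 2, and the median SE was 0.698. Without the patient block 8 of the 20 list calls ended, the medians of ribosomal proteins, oligodendrocyte markers, myelin and homeostatic microglia were -0.07, 0.02, -0.05 and 0.21, and RPL7, CX3CR1 and PTPRZ1 turned to 0.16, -0.14 and 0.08, without the low-quality libraries 11 ended, and GAPDH turned to 0.29 with limma-voom. With 1 pair left out the values nearest to 0 were -0.54 for GAPDH, -0.49 for LDHA, -0.39 for HILPDA, -0.42 for PTPRZ1 and 0.70 for HLA-DPB1.

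Glioma-like nuclei (7 pairs) were compared to ask whether the tumor cells themselves differ between the sites. OPC-like state genes had negative medians in T_SVZ and several immune, stress and glial gene groups positive ones, and no single gene passed. Of 31 OPC-like state genes 26 were negative (median -0.47), led by BCHE (-1.59 ± 0.56), OLIG1 (-1.86 ± 0.74) and OLIG2 (-1.53 ± 0.66), the last 2 transcription factors of the oligodendrocyte lineage, with OLIG2 lower in 7 of 7 pairs. All 15 complement and phagocytosis genes were positive (median 1.17), with MERTK at 0.88 ± 0.45 and the integrin gene ITGB2 at 2.76 ± 1.43. Of 11 MHC class II genes 10 were positive (median 1.003; HLA-DRB1 at 2.48 ± 1.79, in a family of close paralogs). Of 23 interferon response genes 18 were positive (median 0.39), with IFI44L at 0.74 ± 0.41 and IFI6 at 1.48 ± 0.85. Markers of other cell types moved with these groups: 23 of 24 myeloid markers were positive (median 0.73; SLC11A1 at 1.11 ± 0.59, PTPRC at 0.83 ± 0.64), as were endothelial (0.58), astrocyte (0.50; SLC14A1 at 2.06 ± 0.98, AQP4 at 0.86 ± 0.47) and ependymal markers (0.52; CFAP157 at 1.90 ± 0.58, FOXJ1 at 2.35 ± 1.07). Heat shock and unfolded protein genes (20 of 21 positive, median 0.47; HSPA1B at 1.62 ± 0.97, a gene with a near-identical copy), mesenchymal-like state (28 of 34, 0.30), astrocyte-like state (26 of 38, 0.13) and mitochondrially encoded genes (12 of 13, 0.63) were positive as well. Of the 13 mitochondrially encoded genes, 3 were among those at 0 UMIs in some libraries.

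In glioma-like nuclei these 12 of 34 lists passed camera, 11 upward and 1 downward, and 0 passed with an estimated correlation (adjusted p = 0.262 for interferon response, and 0.79 to 0.816 for the others). Adjusted over the list alone, 0 members of any list passed, as over all genes. NPC-like state (-0.34) and the cell cycle (0.0010) did not pass. edgeR found 0 of 14760 genes changed, with 125 at an unadjusted p below 0.05 (0.847%, where chance gives 5%). DESeq2 found 0, with 352 unadjusted. The genes named by rule were WLS (0.68 ± 0.24, in 7 of 7 pairs), a carrier of Wnt ligands, GHR (1.29 ± 0.50), the growth hormone receptor, C21orf62 (0.95 ± 0.33), NIPAL3 (1.01 ± 0.38), RTN1 (1.10 ± 0.43) and SLC4A10 (1.31 ± 0.51) on the positive side, and SYCP2 (-1.10 ± 0.34) and RSRC1 (-0.95 ± 0.32), each in 7 of 7 pairs, UST (-1.05 ± 0.35), BRINP2 (-1.33 ± 0.44) and TMEM108 (-1.17 ± 0.40) on the negative side, with adjusted p = 1 each. Pooled over all libraries, not the 7 pairs alone, T_SVZ nuclei lay mostly in clusters 34, 9, 36, 24, 21 and 18. T_Mass nuclei lay mostly in clusters 30, 10, 18, 26, 25 and 9. Clusters were made without batch integration, and how far single patients fill them was not tested. The summed counts rested on 22 to 3693 nuclei per T_SVZ library and 76 to 3993 per T_Mass library, and over the 5 pairs with at least 50 nuclei the myeloid marker median was 0.00792. Without the patient block the OPC-like call ended (median -0.29, 21 of 31 negative, adjusted p = 0.156), as did those of mesenchymal-like (0.07), astrocyte-like (-0.01) and ependymal genes (0.41). With 1 pair left out the values nearest to 0 were -1.19 for OLIG1, -0.88 for OLIG2, 1.30 for HLA-DRB1, 1.7 for ITGB2, 0.38 for PTPRC, 0.40 for IFI44L, 0.87 for IFI6, 0.72 for SLC11A1, 1.37 for SLC14A1, 0.83 for SLC4A10, 1.46 for FOXJ1 and 1.01 for HSPA1B.

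Myeloid-like nuclei (10 pairs) were compared to ask whether microglia and macrophages differ between the sites. Genes of MHC class II antigen presentation had a positive median in T_SVZ and ribosomal protein genes a negative one. No single gene passed, and 0 lists passed with an estimated correlation. All 12 MHC class II genes were positive (median 0.37), with CIITA at 0.73 ± 0.25 in 8 of 10 pairs, HLA-DQA1 at 0.47 ± 0.32 and HLA-DPB1 at 0.37 ± 0.34. Of 41 ribosomal protein genes 39 were negative (median -0.83; RPL4 at -1.15 ± 0.89). These 2 of 29 lists passed camera, and neither passed with an estimated correlation (adjusted p = 0.939). Of the 41 ribosomal protein genes, 40 were among the genes at 0 UMIs in some libraries. Without those genes their list could not be tested, so its median may reflect missing counts. Homeostatic microglia genes (16 of 18 positive, median 0.18), lipid and SPP1 macrophage genes (-0.15), glycolysis (-0.27) and hypoxia genes (19 of 24 negative, -0.30) each had a camera adjusted p of 0.157. Without the patient block the median of homeostatic microglia was -0.10, and hypoxia (-0.43) and glycolysis (-0.62) passed (adjusted p = 0.0244 and 0.0357), while MHC class II was at 0.21 and ribosomal proteins at -0.50. With 1 pair left out the values nearest to 0 were 0.23 for HLA-DQA1, 0.11 for HLA-DPB1 and -0.70 for RPL4. Monocyte-derived macrophage genes had a median of -0.14 (adjusted p = 0.566). Glioma markers, which measure another cell type here, had a median of -0.41 (15 of 18 negative, adjusted p = 0.331).

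The genes named by rule in myeloid-like nuclei had small standard errors and adjusted p = 1. MS4A14 (0.64 ± 0.17) and MS4A7 (0.42 ± 0.12), membrane proteins of macrophages, were higher in T_SVZ in 10 of 10 pairs, and ICA1L (0.86 ± 0.24), IQSEC2 (0.37 ± 0.11), MOB1B (0.30 ± 0.09) and NFE2L3 (1.20 ± 0.37) in 8 or 9. GMEB1 (-0.45 ± 0.13) was lower in 10 of 10 pairs, and ARPC2 (-0.34 ± 0.10), a part of the actin nucleating Arp2/3 complex, MANEA (-0.65 ± 0.20), PABPN1 (-0.55 ± 0.18), PPIL2 (-0.35 ± 0.11) and IFT81 (-1.15 ± 0.40) in 8 or 9. edgeR found 0 of 9421 genes changed, with 139 at an unadjusted p below 0.05 (1.48%, where chance gives 5%). DESeq2 found 0, with 238 unadjusted. Adjusted over the list alone, 0 members of any list passed. The self-test recovered 28.7% of genes simulated at a log2 change of 1 and 95.5% at 2. These rates are those of simulated counts and may not hold for the data. Pooled over all libraries, most myeloid-like nuclei of T_SVZ lay in clusters 23 and 22, and those of T_Mass in clusters 22, 23 and 33. Cluster 22 is led by macrophage genes such as CD163, MRC1 and F13A1. It held 37.4% ± 30.8 of the myeloid-like nuclei in T_SVZ and 49.5% ± 34.1 in T_Mass (n = 10 pairs, permutation p = 0.434), a share examined after the clusters were seen.

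Oligodendrocyte-like nuclei (7 pairs) show how a resident cell type differs between the sites. Genes of glycolysis, myelin and the heat shock response had positive medians in T_SVZ. No single gene passed over all genes, and 0 lists passed with an estimated correlation. Of 6 glycolysis genes tested 5 were positive (median 0.87), with the glycolytic enzymes PGK1 at 2.37 ± 0.96 and PGAM1 at 1.80 ± 0.65. Of 18 myelin genes 16 were positive (median 0.17), with MOBP at 0.80 ± 0.26, while CNDP1 was at -0.63 ± 0.19. Of 15 heat shock and unfolded protein genes 12 were positive (median 0.33), with the chaperone gene HSPA1A, which has a near-identical copy, at 1.89 ± 0.79. These 3 of 26 lists passed camera and 0 with an estimated correlation (adjusted p = 0.974). NRCAM, an adhesion molecule among the glioma markers, was the 1 gene of any list that passed when adjusted over the list alone (-3.03 ± 0.82, lower in 6 of 7 pairs). Glioma markers as a list had a median of -0.17 (6 of 7 negative, camera adjusted p = 0.217) and neuron markers of -0.67 (3 of 5 negative, adjusted p = 0.995).

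edgeR found 0 of 8504 genes changed in oligodendrocyte-like nuclei, with 154 at an unadjusted p below 0.05 (1.81%, where chance gives 5%). DESeq2 found 0, with 259 unadjusted. The genes named by rule on the positive side were LGR5 (0.58 ± 0.14), MAN2A1 (0.40 ± 0.12) and GLCE (0.44 ± 0.14), each in 7 of 7 pairs, PDK4 (0.78 ± 0.21), a kinase that inhibits pyruvate dehydrogenase, CNTNAP3 (1.68 ± 0.45) and EFHD1 (0.42 ± 0.13). On the negative side were BEND6 (-1.02 ± 0.21), LAP3 (-0.80 ± 0.17) and BAALC (-1.93 ± 0.50), each in 7 of 7 pairs, NOS1 (-1.79 ± 0.49) and MAML2 (-0.87 ± 0.25), a coactivator of Notch, all with adjusted p = 1. Pooled over all libraries, T_SVZ nuclei lay mostly in clusters 6, 5, 3 and 32, and T_Mass nuclei in clusters 5, 3 and 6. Without the low-quality libraries the glycolysis median was 0.17, and the heat shock call ended at a similar median (0.32, adjusted p = 0.0754). Without the patient block the medians of glycolysis and heat shock genes were 0.51 and 0.56.

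Myeloid-like nuclei of 11 T_SVZ libraries were set against those of 2 N_SVZ libraries to ask how the class differs from that of normal tissue. CECR2 was the 1 gene past the threshold in edgeR. CECR2, a bromodomain protein of chromatin remodeling, fell by 3.13 ± 0.39 log2 units in T_SVZ (edgeR adjusted p = 0.0147), from 7.95 ± 0.15 log2 CPM in N_SVZ to 4.74 ± 0.67 in T_SVZ (mean ± SD), and was lower in 11 of 11 libraries. CECR2 is a protein-coding gene on the plus strand of chromosome 22, 17359949 to 17558151 of GRCh38. Hypoxia genes (23 of 25 negative, median -2.39), glycolysis genes (13 of 13, -2.31) and heat shock and unfolded protein genes (19 of 21, -2.24) had lower values in T_SVZ, and 16, 5 and 8 of their members passed when adjusted over the list alone, against 0 over all genes. Among them were INSIG2 (-3.21 ± 0.59), ANKRD37 (-4.68 ± 0.89), DDIT4 (-2.69 ± 0.57), P4HA1 (-3.21 ± 0.69), a collagen prolyl hydroxylase, the glycolytic enzymes PGK1 (-2.61 ± 0.67) and HK2 (-2.62 ± 0.81), and the chaperones DNAJB1 (-2.57 ± 0.74) and HSP90AB1 (-3.42 ± 1.06). These values came from 1 of the 2 N_SVZ libraries: without N_SVZ replicate 1 the medians were 0.85, 0.48 and 0.44 and no call held.

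**Figure D2:**
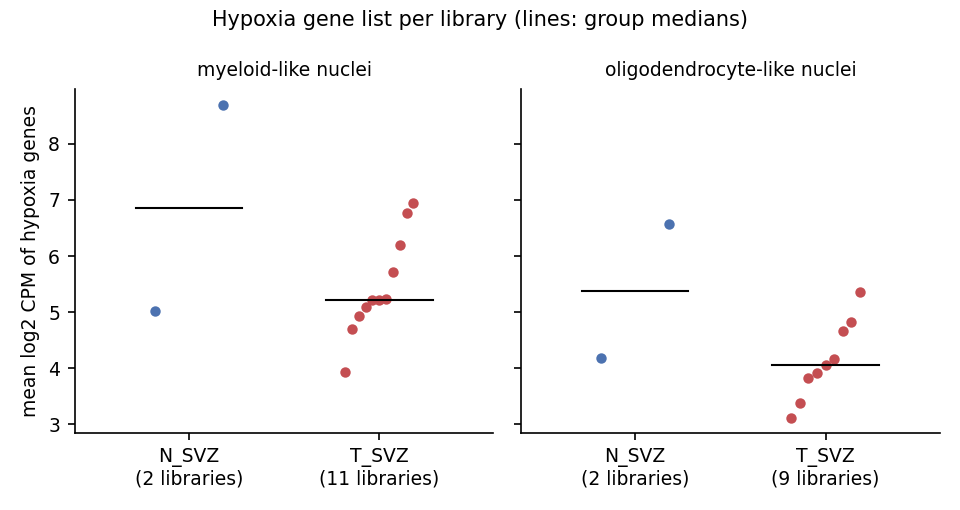
Mean log2 CPM of the hypoxia genes (vertical axis) in myeloid-like and in oligodendrocyte-like nuclei, with 1 point per N_SVZ or T_SVZ library and a line at each group median. The N_SVZ libraries lay at 5.02 and 8.7 in myeloid-like nuclei and at 4.18 and 6.58 in oligodendrocyte-like nuclei, and the T_SVZ libraries at 3.94 to 6.95 and at 3.12 to 5.36.

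Other groups had medians away from 0 in myeloid-like nuclei against N_SVZ, with 0 lists called at an estimated correlation. Of 18 homeostatic microglia genes 17 were negative (median -0.74), with the fructose transporter SLC2A5 at -1.27 ± 0.45, SORL1 at -1.34 ± 0.48 and the receptor CSF1R at -0.68 ± 0.31. Cluster 22, led by macrophage genes, held 8.01% ± 0.301 of the class in N_SVZ and 42.7% ± 34 in T_SVZ (exact permutation p = 0.141). The summed counts cannot tell a change within microglia from another mixture of microglia and macrophages. All 32 cell cycle genes were positive (median 2.20, or 2.16 with genes of up to 3 UMIs in N_SVZ at their bound), with ATAD2 at 1.74 ± 0.63 and FANCI at 1.73 ± 0.65. Mesenchymal-like genes were negative (20 of 29, median -0.73), and CHI3L1 (-5.00 ± 1.19) passed when adjusted over the list alone, with SPP1 at -2.41 ± 0.70. Ribosomal protein genes were negative (40 of 41, median -1.24; RPL3 at -2.12 ± 1.51). These lists and those of hypoxia, glycolysis and heat shock were the 7 of 34 that passed camera, and 0 passed with an estimated correlation (adjusted p = 0.582, and 0.785 for ribosomal proteins). The ribosomal list could not be tested without the genes at 0 UMIs, which hold 40 of its 41 genes. Monocyte-derived macrophage genes had a median of 1.48 (14 of 19 positive, adjusted p = 0.0901), and adjusted over the list alone STAB1 (1.43 ± 0.42) rose and VEGFA (-3.22 ± 0.86) fell. In lists without a call, 1 to 4 members passed that way, as in angiogenesis (1 upward, 3 downward). Markers of other cell types had positive medians without passing: oligodendrocyte markers 1.88 (8 of 9 positive), T and NK lymphocyte markers 2.01 (10 of 11) and astrocyte markers 5.82 (3 of 4), or 1.86, 1.40 and 3.32 with low-count genes at their bound. Pooled over all libraries, most N_SVZ nuclei of the class lay in clusters 23 and 20, and T_SVZ nuclei in clusters 23 and 22. Cluster 20 is led by OLR1, TLR2, HK2 and SPP1. How far each N_SVZ library fills these clusters was not tested, so they may reflect a single library and not normal tissue.

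After CECR2, the genes named by rule in this comparison were ZNF804A (1.83 ± 0.31) and ESR1 (2.88 ± 0.52), the estrogen receptor alpha, on the positive side, and ALAS1 (-3.00 ± 0.48), the first enzyme of heme synthesis, SLC25A37 (-3.15 ± 0.53), a mitochondrial iron importer, RASSF8 (-3.26 ± 0.58), HACE1 (-2.01 ± 0.36) and CBWD2 (-2.52 ± 0.43), which has close paralogs, on the negative side, each in 11 of 11 libraries with edgeR adjusted p = 0.0526. USP54, CEP97, CCDC170 and KAZN had 0 to 2 UMIs per N_SVZ library and UMIs in 11 of 11 T_SVZ libraries. Of 10741 genes tested 1389 had an unadjusted p below 0.05, and DESeq2 called 285. Without N_SVZ replicate 1 the call of CECR2 ended (-2.99, adjusted p = 0.0804), and edgeR called 0 genes. Without replicate 2, where the lone library is assumed to vary like the T_SVZ libraries, it called 1171. With DESeq2 size factors it called 21. Without replicate 1 the values were -0.55 for SLC25A37, -0.53 for HACE1, -0.88 for CBWD2, -1.36 for RASSF8, -0.36 for SPP1, -0.37 for DDIT4, -0.44 for SLC2A5, -0.85 for SORL1, -1.0 for ALAS1 and -0.01 for VEGFA. The same fit gave positive values for INSIG2, ANKRD37, P4HA1, PGK1, HK2, DNAJB1, HSP90AB1, CHI3L1 and RPL3, and mesenchymal-like and ribosomal medians of 0.82 and 2.19. Without replicate 2 the homeostatic microglia call ended (median -0.48), and the cell cycle median was 4.62 and FANCI at 2.79, against 1.77 and 1.18 without replicate 1.

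Oligodendrocyte-like nuclei of 9 T_SVZ libraries were set against those of 2 N_SVZ libraries, in which the class held 1721 and 2883 nuclei. The question was again the difference from normal tissue. Heat shock, immediate early, hypoxia, glycolysis, myelin and cholesterol synthesis genes had negative medians in T_SVZ, and interferon response genes a positive one. The first 4 turned without N_SVZ replicate 1, and no single gene passed over all genes. All 19 heat shock and unfolded protein genes (median -1.80) and all 12 immediate early genes (median -1.65) were negative, with ATF3 (-3.49 ± 0.71) and HSPH1 (-2.19 ± 0.63) and, of the early genes, ATF3 and BTG2 (-2.61 ± 0.66) passing when adjusted over the list alone. HSPA1A was at -2.79 ± 0.97 and NR4A2 at -1.77 ± 0.63. Of 24 hypoxia genes 21 were negative (median -1.47), and 5 passed over the list alone, among them P4HA1 (-2.67 ± 0.62), PFKFB3 (-1.77 ± 0.46) and ERO1A (-1.61 ± 0.43). All 13 glycolysis genes were negative (median -1.08; GPI at -1.07 ± 0.43). Of 18 myelin genes 17 were negative (median -0.43), with ASPA at -1.14 ± 0.49 and ENPP2 at -0.89 ± 0.35, and of 20 cholesterol synthesis genes 15 (median -0.34), where INSIG1 (-2.99 ± 0.66), which restrains cholesterol synthesis, passed over the list alone and SREBF2 was at -0.96 ± 0.30. Of 17 interferon response genes 15 were positive (median 0.84), with STAT2 at 0.84 ± 0.33 and PARP14 at 3.32 ± 1.24, and of these genes SAMD9 alone (4.95 ± 1.29, in 6 of 9 libraries) passed over the list alone. Mitochondrially encoded genes (13 of 13, median 2.50; MT-ND1 at 3.51 ± 1.995) and OPC markers (7 of 8, median 2.72; LHFPL3 at 2.58 ± 0.87) were positive. Before nuclei were filtered, mitochondrially encoded genes held 0.2307% and 0.5113% of UMIs in the N_SVZ libraries and 0.001447% to 7.04% in T_SVZ. Of these 13 genes, 3 were among those at 0 UMIs in some libraries.

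In oligodendrocyte-like nuclei against N_SVZ, 9 of 33 lists passed camera, 3 upward and 6 downward, and 0 passed with an estimated correlation (adjusted p = 0.39 for interferon response, and 0.701 to 0.924 for the others). Markers of myeloid cells (median 1.60, 11 of 14 positive, adjusted p = 0.271) and astrocytes (2.17, 7 of 8, adjusted p = 0.453) had positive medians as well. edgeR found 0 of 11560 genes changed, with 469 at an unadjusted p below 0.05, and DESeq2 found 2. The genes named by rule were SCN8A (2.43 ± 0.52), a neuronal sodium channel, NCK2 (1.26 ± 0.34), CDH8 (1.44 ± 0.41), P3H2 (1.48 ± 0.46), RBM3 (1.45 ± 0.45) and ZC3HAV1 (3.69 ± 1.17), and on the negative side ZNF331 (-2.49 ± 0.48), ELOVL5 (-2.25 ± 0.49), a fatty acid elongase, and LRRTM2 (-2.29 ± 0.53), besides ATF3, INSIG1 and P4HA1, each in 9 of 9 libraries with adjusted p of 0.982 or 1. Pooled over all libraries, N_SVZ nuclei lay mostly in clusters 4 and 6, and T_SVZ nuclei in clusters 6, 5, 3 and 32. How far each N_SVZ library fills clusters 4 and 6 was not tested. Without N_SVZ replicate 1 the medians of hypoxia, glycolysis, heat shock and immediate early genes were 0.13, 2.36, 1.01 and 3.48, BTG2 was at -0.09, PFKFB3 at -0.17, INSIG1 at -0.86, SREBF2 at -0.47, LRRTM2 at -0.82, NR4A2 at -0.74, GPI at -0.43 and ENPP2 at -0.48, the values of P4HA1, ERO1A, HSPH1, HSPA1A, ATF3, ZNF331 and ELOVL5 were positive, and the cholesterol call ended (median 0.01), as did the interferon call at a similar median (0.76). Without replicate 2 the calls of mitochondrially encoded genes and OPC markers ended at similar medians (2.49 and 2.71), edgeR called 40 genes, and CDH8 was at 2.17, PARP14 at 6.16 and MT-ND1 at 5.38, against 0.95, 2.28 and 2.62 without replicate 1.

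**Figure D3:**
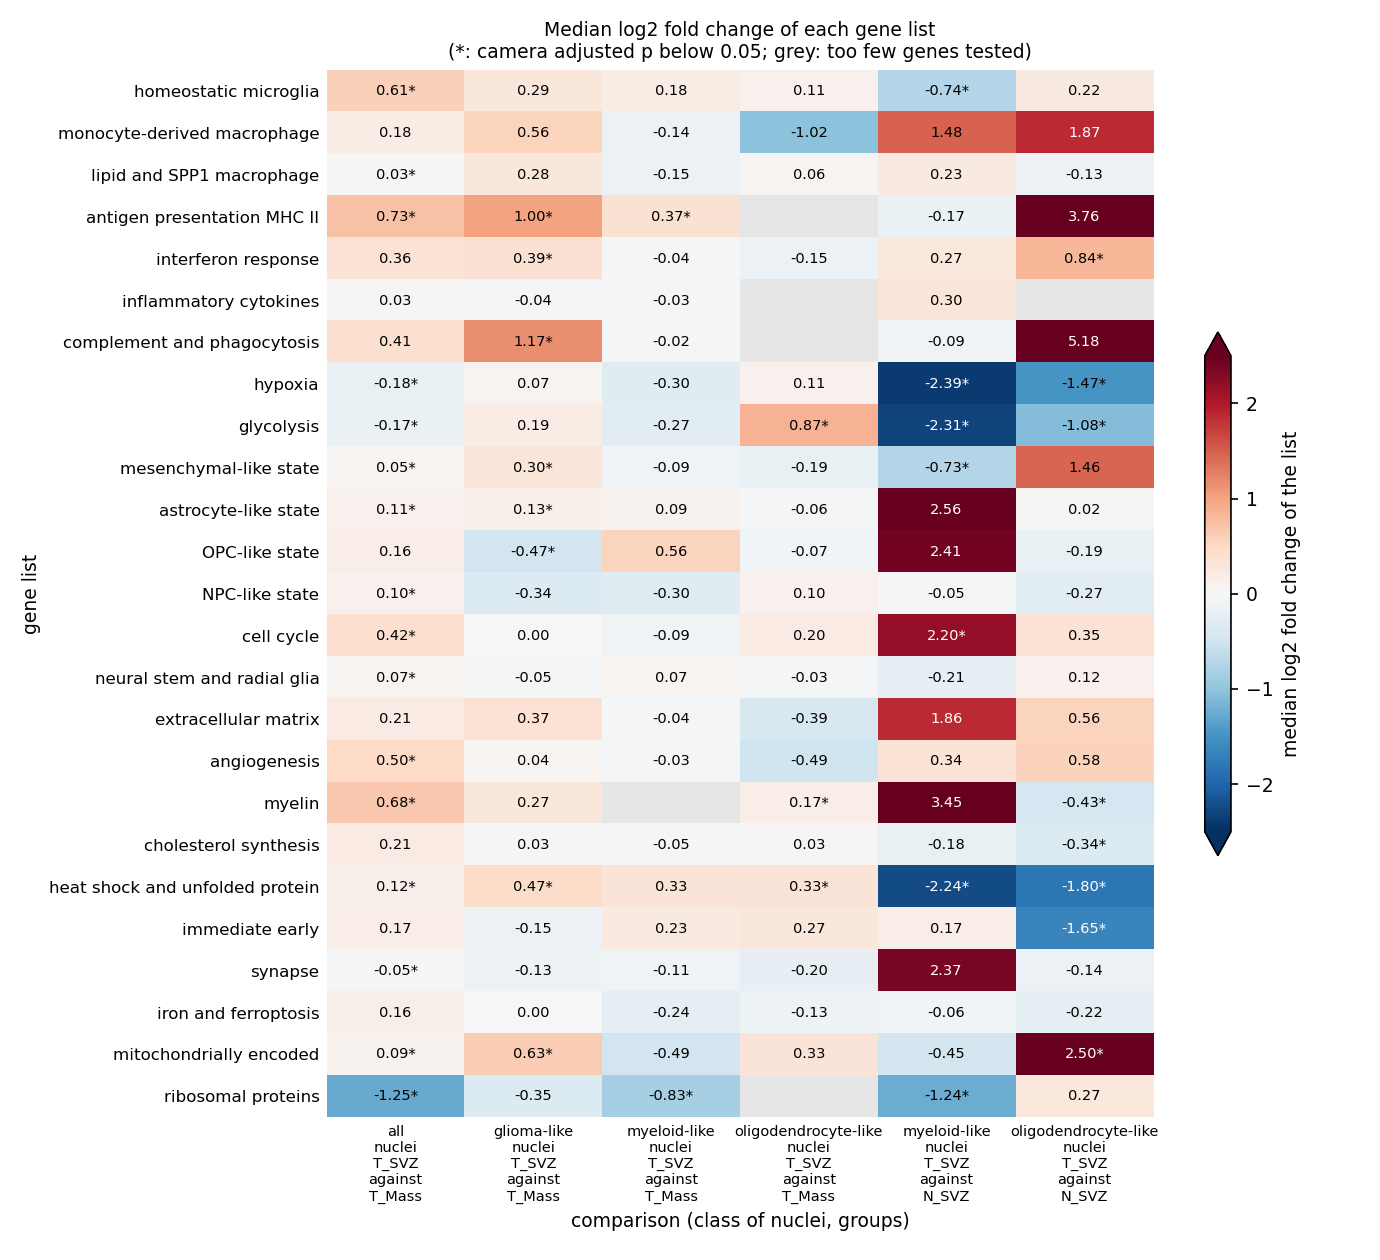
Median log2 fold change over the tested genes of each of the 25 gene lists (vertical axis) in the 6 comparisons (horizontal axis), with red for positive and blue for negative medians and a star where the camera adjusted p was below 0.05 at a preset correlation of 0.01. Hypoxia genes stood at -2.39 and -1.47 in myeloid-like and oligodendrocyte-like nuclei against N_SVZ and at -0.18 in all nuclei against T_Mass; 0 starred lists passed with an estimated correlation.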

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

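The tests of 1 N_SVZ library, free RNA, myeloid RNA, few nuclei and low-quality libraries below had their expected values written before they were run. The test of ribosomal genes at 0 UMIs and the regrouping of pairs were chosen after other results had been seen, as were the 3 patterns themselves. The requirement that a value clear its limit by more than its spread was also added after the values of the ribosomal and free RNA tests were known.

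Some named genes had 1 value far from the others, by the gap to the nearest value divided by the range. In the 7 pairs of glioma-like nuclei this was SYCP2 (0.675; log2 differences from -5.87 to -0.10, median -0.91). In the 10 pairs of myeloid-like nuclei they were HLA-DQA1 (0.529; -0.99 to 2.91, median 0.56) and HLA-DPB1 (0.479; -0.66 to 3.06, median 0.12). In oligodendrocyte-like nuclei of 9 T_SVZ libraries against the N_SVZ mean they were CDH8 (0.547; 0.11 to 2.12, median 1.41), ATF3 (0.529; -6.41 to -1.12, median -2.17), HSPH1 (0.669; -7.46 to -0.23, median -1.54), ENPP2 (0.533; -2.30 to -0.15) and GPI (0.513; -3.77 to -0.51, median -0.91). These are 8 of 86 genes looked at, and chance gives about 1 in 20.

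Genes outside the shared list, which no comparison used, held more of the UMIs in many tumor libraries than in N_SVZ. Their median share was 18.3% in 12 T_Mass libraries (11.4% to 45.6%) and 19.7% in 10 T_SVZ libraries (16.4% to 25.1%), against 15.7% and 17.5% in the N_SVZ libraries. The share lay above both N_SVZ libraries in 7 of 12 T_Mass and 8 of 10 T_SVZ libraries. The difference was not tested.

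Hypoxia genes had negative medians in T_SVZ against N_SVZ in myeloid-like and oligodendrocyte-like nuclei. The value nearest to 0 against a single N_SVZ library was 0.327 in myeloid-like nuclei, with -3.53 against the other library, and the values were -2.93 and -0.222 in oligodendrocyte-like nuclei, so that 1 N_SVZ library carried the difference. Free RNA of 1 source would add the hypoxia genes in about the same ratio to both classes. The SD over 21 genes of the log2 ratio was 1.53 (lower 95% bound 1.17), above the limit of 1 set beforehand. The spread between libraries also widens this SD and is not in the bound, so the test cannot exclude free RNA. Whether the tissue of that N_SVZ library was short of oxygen in life or during handling was not tested.

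Myeloid markers had a positive median in glioma-like nuclei of T_SVZ. With at least 50 glioma-like nuclei per library (5 pairs) the median was 0.00792, which places the difference in pairs with few nuclei. Over the 7 pairs, the marker median and the ratio of myeloid-like shares had a Spearman rho of 0.714 (exact permutation p = 0.0881), which leaves RNA from myeloid cells open. The marker median was positive in 4 of 7 pairs, and no biological explanation was tested.

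Ribosomal protein genes had a negative median in all nuclei of T_SVZ. Without the low-quality libraries the median was -1.07, with 41 of 41 genes below 0, but the pair medians ran from -12 to 11.6. Over the 5 pairs without a ribosomal gene at 0 UMIs the median was -0.866 (pair medians -3.79 to 3.62, 4 of 5 negative). The first value leaves library quality open as an explanation, and the second leaves open the ribosomal genes at 0 UMIs. With 5 pairs no exact permutation p can fall below 0.0625, so the second test could not have excluded them. For both values, the spread between pairs was wider than the shift. An exact permutation test of the pair medians of all 12 pairs gave p = 0.349. No biological explanation was tested.

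T_SVZ and T_Mass were also swapped within pairs to see how many genes other groupings give. With 0 genes in the real grouping, every grouping reaches as many (40 of 40 for all nuclei, 64 of 64 for glioma-like, 100 of 100 for myeloid-like and 64 of 64 for oligodendrocyte-like nuclei), so this count can exclude nothing. The highest numbers in the other groupings were 7, 0, 1 and 1. At an unadjusted p below 0.05 the real numbers were 75, 125, 139 and 154, and as many or more genes were reached in 28, 59, 93 and 35 of these groupings, the real grouping included. The highest numbers in the others were 724, 1675, 974 and 1101.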

How the results depend on the processing

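The alternatives chosen after seeing the data are those so named in the processing section, and the cause of each change below was not tested. Between T_SVZ and T_Mass, edgeR called 0 genes in each of the 4 comparisons under every alternative run for it, as did DESeq2 and limma-voom in 1 fit each. The low-quality libraries did not enter the fit of glioma-like nuclei, and 0 of 8 classes passed in any comparison of shares under any alternative. With 1 N_SVZ library left out no class could pass, since too few groupings remain. Of 136 genes named with a value, 20 turned direction under at least 1 alternative, as did 14 of 24 shares and the test of 12 of 53 called lists, where the sign is that of camera and not of the median. Recovery of a simulated log2 change of 2 was lowest in all nuclei (1.03%) and in myeloid-like nuclei against N_SVZ (5.13%), and the comparisons with N_SVZ rest on 2 libraries.

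In myeloid-like nuclei against N_SVZ, 1 gene became 21 with DESeq2 size factors, 285 with DESeq2, 46 with bias-adjusted deviances, 4 with limma-voom, and 24 without the genes at 0 UMIs and the library of few genes. Leaving out each N_SVZ replicate gave 0 to 1171. In oligodendrocyte-like nuclei, 0 genes became 2 with DESeq2 and 2 with bias-adjusted deviances, and 0 to 40 without each N_SVZ replicate. Of 53 list calls, 0 stayed with an estimated correlation.

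Without the replicate block 49 lists were called, and in all nuclei RPL7 turned to 0.16, CX3CR1 to -0.14, PTPRZ1 to 0.08 and myelin to -0.05, while the block changed no count of genes. GAPDH turned to 0.29 with limma-voom. Without the genes at 0 UMIs, the test of SPP1 macrophage genes (median -0.01) and of astrocyte-like genes (-0.05) turned upward in all nuclei. Without the low-quality libraries, the test of astrocyte-like genes (median 0.06) and of heat shock genes (0.0015) turned upward in all nuclei. Lists called numbered 43 without the genes at 0 UMIs, 52 with DESeq2 size factors and 54 without the low-quality libraries, and 57 and 51 without N_SVZ replicate 1 and 2.

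Shares turned as follows, in points. T_SVZ minus T_Mass: without the shorter feature list glioma-like 11.96, myeloid-like -1.468 and lymphocyte-like -0.08554, at 1000 UMIs oligodendrocyte-like 0.02235, without the low-quality libraries astrocyte-like -0.188, among nuclei that are not glioma-like OPC-like 0.04171. T_SVZ minus N_SVZ: endothelial-like -0.3631 without the shorter feature list, astrocyte-like -0.7765 without the low-quality libraries. T_Mass minus N_SVZ: endothelial-like 0.6127 at 1000 UMIs, 0.0202 with doublets, 3.044 among nuclei that are not glioma-like and 0.07257 without the low-quality libraries, neuron-like 1.893 among nuclei that are not glioma-like, astrocyte-like 0.1968 at 1000 UMIs and 0.2006 among nuclei that are not glioma-like.

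With each replicate left out in turn, shares ranged as follows. T_SVZ minus T_Mass: glioma-like -10.31 to 4.852, oligodendrocyte-like -6.07 to 4.386, myeloid-like -1.984 to 3.019, lymphocyte-like -0.1937 to 1.084, endothelial-like -0.5071 to 1.313, neuron-like -4.248 to -0.3417, astrocyte-like -0.1492 to 5.999, OPC-like -0.3817 to 0.1295. T_SVZ minus N_SVZ: endothelial-like -0.5278 to 1.395, OPC-like -2.905 to 0.296. T_Mass minus N_SVZ: endothelial-like -1.01 to 0.9126, astrocyte-like -1.308 to 0.7104, OPC-like -2.766 to 0.435.

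With each N_SVZ replicate left out, log2 values in myeloid-like nuclei ranged from -3.31 to 0.85 for hypoxia, -3.22 to 0.48 for glycolysis, -1.09 to 0.82 for mesenchymal-like and -2.20 to 2.19 for ribosomal genes, -3.12 to 0.44 for heat shock genes (median alone), and for ANKRD37 -5.66 to 0.91, CHI3L1 -6.02 to 1.08, DNAJB1 -3.48 to 0.44, HK2 -3.51 to 0.06, HSP90AB1 -4.41 to 2.67, INSIG2 -4.14 to 0.12, P4HA1 -4.17 to 1.16, PGK1 -3.56 to 0.95 and RPL3 -3.05 to 0.93. In oligodendrocyte-like nuclei they ranged from -2.32 to 0.13 for hypoxia, -1.86 to 2.36 for glycolysis, -2.56 to 1.01 for heat shock and -2.43 to 3.48 for immediate early genes, -0.71 to 0.01 for cholesterol synthesis (median alone), and for ATF3 -4.44 to 0.20, ELOVL5 -3.12 to 0.18, ERO1A -2.36 to 0.02, HSPA1A -3.72 to 0.80, HSPH1 -3.07 to 0.45, P4HA1 -3.59 to 0.49 and ZNF331 -3.36 to 0.03.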

Other observations

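The share of macrophage-type nuclei was chosen after the clusters were seen, and so was its test. Cluster 22, led by CD163, MRC1 and F13A1, held 8.01% ± 0.301 of the myeloid-like nuclei in the N_SVZ libraries, 42.7% ± 34 in 11 T_SVZ libraries (exact permutation p = 0.141) and 55.4% ± 32.8 in 13 T_Mass libraries (exact permutation p = 0.0381, adjusted p = 0.114). The share was above both N_SVZ libraries in 10 of 11 T_SVZ and 13 of 13 T_Mass libraries.

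The unnamed glial clusters held 0.607% and 42.7% of the nuclei of the N_SVZ libraries.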
